A study of Homo sapiens with 17 samples.

How the data were processed

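Gene expression was measured by RNA-seq in Kasumi-1 cells, an established human acute myeloid leukaemia line that carries the t(8;21) translocation and expresses its fusion protein AML1-ETO. Cells were infected with lentiviruses that express short hairpin RNAs and were harvested 4 days after infection, per the labels' protocols. There were 10 RNA-seq libraries: 1 each for hairpins against AML1-ETO, E2A, LYL1, LDB1 and LMO2 with 1 shared control (control 1), 1 for HEB with its own control (control 2), and 1 for a double knockdown of HEB and E2A with its own control (control 3). The titles state which control belongs to which knockdown. Binding of AML1-ETO, HEB, E2A and LMO2 was measured by ChIP-seq in the same line, with 1 peak list per factor. The 3 input libraries were not used here.

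The RNA libraries were made from RNA selected with oligo(dT) beads and were sequenced from both ends, per the labels' protocols. Reads were aligned with TopHat to the human build hg19, per the submitters' processing notes, and the version is not given in the sources used here. The authors deposited 1 table per library with 23221 genes and, for each gene, an RPKM value, an aligned total and an exon length. Per the file headers the library totals are in bases, and the deposited RPKM is aligned bases per kilobase of exon per megabase aligned. In every library the coverage per exon base flattened near 102, which is 2 strands times a step of 51 bases seen in the low totals. RPKM differences between abundant transcripts are therefore compressed. The value of 102 is not a strict limit: 2 to 13 genes per library lay above it, with MPO at 107.5 to 125.7. Between 54.5% and 59.0% of the low totals were multiples of 51. The libraries held between 1555 and 1650 megabases, except the double knockdown with 517.9 and control 3 with 856.0. These tables give aligned bases and not read counts, so no count model and no counting interval was used.

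For ChIP-seq, cells were cross-linked with a protein cross-linker and formaldehyde before immunoprecipitation, per the labels' protocols. Coordinates are on build hg18, per the submitters' processing notes, and the peak caller is not given in the sources used here. The peak lists have no header. From the values of the deposited lists, the authors give for each peak a start and end, a score that looks like a log10 p-value, a second unlabelled score, the position and height of the highest pile of reads (a coverage signal that is not normalized), and the place of that position as a percent of the peak's width. Whether positions are counted from 0 or 1 is not stated, so coordinates are printed as the files give them. The score that looks like a log10 p-value reached no weaker than -15 for 3 lists and -5 for LMO2. Scores and heights are the authors' own and were used only to rank or filter peaks within a list.

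Changes were computed on log2(RPKM + 0.5), which understates the change of genes with low values. With 1 library per knockdown there was no replicate check for a single knockdown, and a rule of size was used in place of a test. A gene passed the rule when it differed from its own control by at least 1 on the log2 scale, had an RPKM of at least 1 in either library, and differed by more than any 2 of the 3 controls differed from each other. Below, "higher" and "lower" genes of a knockdown are those past this rule. The named genes are the 10 with the largest increase and the 10 with the largest decrease for AML1-ETO, HEB and the double knockdown, and the 6 in each direction for the other 4, among genes past the rule with an RPKM of at least 5 in either library. Some genes that this rule selects are not reported here. Every hairpin target was also named, and from each of 26 gene lists the 4 members with the largest change among those with an RPKM of at least 5. A list's median log2 fold change was placed among 10000 random lists of the same size matched on mean expression in 10 bins, as a description of these libraries.

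Effects common to the 7 knockdowns were tested against the 3 controls with limma 3.58.1 in R 4.3.3 (empirical Bayes with an intensity trend, control set as a block, Benjamini-Hochberg adjustment, threshold 0.05) over genes with an RPKM of at least 1 in at least 3 libraries. Gene lists were tested in the same fit with camera, with a preset and with an estimated correlation, and with fry. A second limma fit set each knockdown against the 3 controls with the lone knockdown library assumed to vary like the controls. The 3 controls were separate libraries of 1 cell line, and the labels do not say whether they came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Correlations between knockdowns were computed across genes, which are not independent replicates. Beside them stand values from 100 simulations of unchanged libraries and controls, with independent noise of the size seen between controls 1 and 2. Peak overlap was counted with bedtools 2.31.1 at a minimum overlap of 1 base, beside 1000 random shifts of the other list within each chromosome, with exact binomial 95% intervals that cover counting error only. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 were used.

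The fits and the size rule were tested on simulated data with 200 changed genes, the list percentiles on 100 lists of 20 genes and the overlap step on 5000 peaks. Camera, fry and the correlations were not tested in this way. The common effect fit recovered 89% of genes changed by a log2 of 1 and 97% of those changed by 2, with 6 false calls among 13719 genes. The fit of shAML1-ETO against the controls recovered 51% and 75%, with 12 false calls among 14212 genes. The size rule recovered 91% of genes changed by 1.5 and 95% of those changed by 2.5, with 54 false calls among 14212 genes. For the list percentiles, 6% of unchanged lists and 100% of shifted lists lay beyond 95% of random lists, and the overlap step found 2000 of 2000 planted overlaps.

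The groups, the size rule, the tests, the gene lists and the rule for named genes were fixed before the data were examined, as were alternatives for the pseudocount, low-value filter, scaling, choice of control, size limit and peak overlap. Values corrected for the coverage ceiling, quantile normalization for the size rule, a filter on short genes and a fit without the 2 shallow libraries were added after the data were seen. Genes could not be assigned to peaks because no hg18 annotation was used here.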

Results

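The study asked how Kasumi-1 cells respond when single members of a protein complex built around AML1-ETO are depleted, and where members of that complex bind. RNA-seq covered 7 knockdown libraries and 3 control libraries, and ChIP-seq covered 4 factors with 1 peak list each. AML1-ETO joins the DNA-binding part of RUNX1 to RUNX1T1 (ETO). HEB (gene TCF12) and E2A (gene TCF3) are E proteins, a class of basic helix-loop-helix transcription factors, LYL1 is a helix-loop-helix partner of E proteins, LMO2 is a bridging adaptor and LDB1 binds LMO2. There was 1 library per knockdown, so values of a single knockdown carry no replicate error. Each is set against its own control, and the size rule also uses the differences between the 3 controls.

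Every targeted gene was lower in its knockdown than in its own control, by modest amounts on the deposited scale. In the shE2A library TCF3 was 39.3 RPKM against 53.4 in control 1, or 73.5% of control. LYL1 stood at 79.4% in shLYL1 (40.1 against 50.5 RPKM), LDB1 at 76.6% in shLDB1 (36.2 against 47.2) and LMO2 at 82.0% in shLMO2 (31.3 against 38.2). TCF12 was at 76.8% in shHEB (31.9 against 41.6) and 67.7% in the double knockdown (32.0 against 47.3), where TCF3 was at 77.4% (55.6 against 71.8). That TCF3 value was below control 3 but above the deeper controls 1 and 2 (53.4 and 52.9). In shAML1-ETO, RUNX1T1 was 30.5 RPKM against 37.5 in control 1 and a mean of 38.5 ± 3.56 in the controls (SD, n = 3), or 81.5% of control 1. RUNX1, which the fusion and the normal allele both feed, was 42.2 against 47.3, or 89.3%. In knockdowns aimed at other genes, levels as percent of own control lay between 97.0% and 121% for RUNX1T1, 97.6% and 119% for RUNX1, 89.2% and 99.9% for TCF3, 92.8% and 133% for LYL1, 98.0% and 122% for LDB1, 102% and 121% for LMO2, and 94.8% and 101% for TCF12. These genes lie where coverage is compressed: with values corrected for the coverage ceiling, TCF3 in shE2A came to 54.9%, LYL1 to 64.9%, LDB1 to 63.2% and RUNX1T1 to 72.8% of control.

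**Figure D1:**
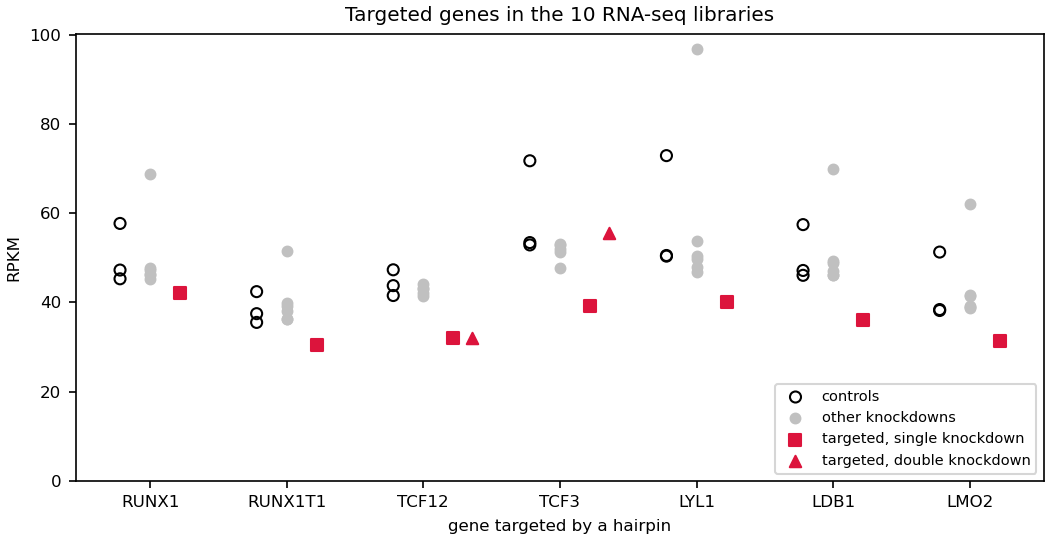
RPKM (vertical axis) of the 7 genes targeted by hairpins, in the 3 control libraries (open circles), the knockdowns aimed at other genes (grey) and the knockdowns aimed at that gene (red squares for single knockdowns, red triangles for the double knockdown). TCF3 stood at 39.3 RPKM in shE2A and between 52.9 and 71.8 in the controls.

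In shAML1-ETO some genes of myeloid cells, such as TYROBP and RNASE3, were higher, and some genes of progenitors, such as FLT3 and BAALC, were lower. Myeloid genes did not all rise: of 9 monocyte genes 2 were higher and 1, ITGAX (-1.42), was lower, with a list median of 0.32. C11orf21 went from 0.274 to 20.7 RPKM (log2 fold change 4.78), TYROBP, a signalling adaptor of myeloid cells, from 0.222 to 13.6 (4.29), the tetraspanin CD9 from 0.174 to 8.18 (3.69) and the selectin ligand SELPLG from 2.53 to 34.6 (3.53). TSPAN32 (3.41), SERPINB10 (3.34), PRAM1 (3.32), CEACAM6 (3.35) and CEACAM4 (3.31) were also among the largest increases, and the CEACAM genes are close paralogs whose reads are uncertain. TM4SF1 fell from 17.8 to 0.521 RPKM (-4.16), DUSP27 by 3.76 on the log2 scale, the VEGF receptor FLT1 from 5.96 to 0.115 (-3.39) and PADI3 from 27.5 to 2.31 (-3.31). AFAP1L1 (-3.41), ADAM28 (-3.26), PDZD2 (-3.20), the chemokine receptor CCR4 (-3.16), OLFML2A (-3.08) and HPSE (-3.04) were the other large decreases.

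Of 22 measured granule and granulocyte genes, 3 were higher in shAML1-ETO and 0 lower: RNASE3 (3.11) and S100A8 (2.77), proteins of granulocyte granules and cytosol, and BPI (1.76). The list's median of 0.18 lay above all 10000 random lists (percentile 100). Extreme places were common: 10 of 26 lists lay beyond 95% of random lists in shAML1-ETO, beside 1.3 expected by chance. The number was 10 in shE2A and shLDB1, 8 in shLYL1 and shLMO2, 3 in shHEB and 12 in the double knockdown. Random lists were matched on expression and not on correlation between members, so percentiles here and below are descriptions and not tests. Of 19 stem and progenitor genes 6 were lower and 0 higher, among them MYCN (-2.08), TIE1 (-2.07), the receptor kinase FLT3 (-1.49) and BAALC (-1.31), with a median of -0.24 (percentile 0). The list of genes reported earlier as moved by AML1-ETO had 3 higher and 1 lower of 27, with TSPAN32 and OGG1 (2.18) higher and CDKN1A, an inhibitor of cyclin-dependent kinases, at -2.81. Among E protein partners and targets, ID3 fell by 2.91 on the log2 scale while ID2 (1.49) and BCL6 (1.04) were higher. The interleukin-6 receptor IL6R was higher by 3.14, the NK and T cell gene NKG7 by 2.69 and the eosinophil peroxidase EPX by 1.81, whereas the glucose transporter SLC2A3 was at -1.96. The list of surface and signalling receptors as a whole stayed near 0 (median -0.02, percentile 18.4), with 2 higher and 1 lower of 22. In total 272 genes were higher and 305 lower, where a simulated unchanged library gave a mean of 56.2 genes past the rule.

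The fit against all 3 controls called 12 genes higher and 18 lower in shAML1-ETO (limma, adjusted p under 0.05, with the lone library assumed to vary like the controls, so that p rests on the spread of 3 controls and cannot tell the knockdown from a deviation of that library). The simulation of this fit held 200 planted changes, so its false calls, given above, are not a background for the calls made here. SLC44A2 changed by -2.02 ± 0.14 (SE; adjusted p = 0.0109), PTRF by -2.49 ± 0.16 (adjusted p = 0.0109), CDKN1A by -2.83 ± 0.23 (adjusted p = 0.0250), BAALC by -1.26 ± 0.14 (adjusted p = 0.0365), CD9 by 3.79 ± 0.39 (adjusted p = 0.0365) and C11orf21 by 4.77 ± 0.51 (adjusted p = 0.0365). SLC44A2 and PTRF were singled out after their values were seen. The count depended on the controls: it was 52 higher and 29 lower without control 1, 99 and 34 without control 2, and 201 and 376 without the shallow control 3. In the other 6 knockdowns limma called 0 genes, with 329 (shE2A), 89 (shLYL1), 566 (shLDB1), 135 (shLMO2), 85 (shHEB) and 2904 (double) at an unadjusted p under 0.05. Without control 3 the shallow double knockdown stood only against the deep controls 1 and 2, so its calls there cannot be told from depth.

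Knockdown of E2A raised CSF1R, the receptor of macrophage colony-stimulating factor, from 0.613 to 10.6 RPKM (3.32). CHI3L1 (3.09), THBS4 (2.61), PRAM1 (2.31), SELPLG (2.27) and ELOVL3 (2.17) were the next largest increases. OLFML2A (-2.45), TM4SF1 (-2.39), PADI3 (-2.35), the scavenger receptor STAB1 (-2.34), the natriuretic peptide receptor NPR3 (-2.19) and CD48 (-2.18) were lowest, and TM4SF1 (-1.30) no longer passed against the mean of the 3 controls. The inhibitors of E proteins ID3 (-1.84) and ID1 (-1.15) were both lower, and the list of E protein partners and targets had a median of -0.29 (percentile 0.01). That list holds TCF3 itself, the hairpin target (-0.44). Inflammatory genes also lay low, with 5 of 16 lower, including IL1B (-1.73), CXCL2 (-1.51) and ICAM1 (-1.48), 1 higher, and a median of -0.26 (percentile 0.01). The monocyte list had a median of 0.47 over 9 genes (percentile 99.98), with 2 higher and 1 lower. In all, 154 genes were higher and 97 lower, and 153 and 153 with quantile normalization.

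LDB1 knockdown gave 241 higher and 76 lower genes, and 265 and 141 with quantile normalization. CSF1R reached 11.5 RPKM (3.42), and CLEC12A (3.34), CEACAM4 (3.21), CHI3L1 (3.20), the purinergic receptor P2RY13 (3.03) and SERPINB10 (2.81) followed. S100A8 (2.81) and RNASE3 (1.66) were the 2 of 22 granule genes past the rule, and the list's median was 0.10 (percentile 99.96). AFAP1L1 (-2.63), CCR4 (-2.36), the ETS factor ETV4 (-2.14), NPR3 (-2.07), FLT1 (-1.95) and the cell cycle inhibitor CDKN1C (-1.93) were lowest. Of 20 stem and progenitor genes 3 were lower, with CD109 at -1.59 and TIE1 at -1.46 beside NPR3. Interferon response genes had a median of 0.26 over 25 members (percentile 99.86), with 1 past the rule; OASL (1.13), IFIT2 (1.04) and IRF7 (1.01) did not pass it.

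LMO2 knockdown gave 74 higher and 33 lower genes, where a simulated unchanged library gave a mean of 56.2 past the rule. Without the condition on the controls 183 genes passed, beside 106 between controls 1 and 2. CSF1R (2.70) again led the increases, ahead of IGSF3 (1.89), the B cell receptor CD22 (1.82), AOAH (1.56), CCR1 (1.55) and WNT5B (1.53). CCR4 (-1.95), PAG1 (-1.91), NPR3 (-1.85), MYCN (-1.62), TPSD1 (-1.34) and ETV4 (-1.27) were the named decreases. TPSD1 (-0.85) and ETV4 (-0.80) no longer passed against the mean of the 3 controls, nor did IGSF3, AOAH, CCR1 and WNT5B with a pseudocount of 0.1. The monocyte list had the highest median of the 26 lists in this knockdown, 0.69 over 9 genes (percentile 100), although CSF1R alone passed the rule; MS4A7 was at 0.86 and CD68 at 0.69.

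LYL1 knockdown gave the fewest lower genes, with 74 higher and 12 lower, and 48 and 32 with quantile normalization. A simulated unchanged library gave a mean of 56.2 genes past the rule. Without the condition on the controls 135 genes passed, where controls 1 and 2 differed from each other in 106. Replication-dependent histone genes, which form the core of new chromatin, stood out: HIST1H3J (1.74), HIST1H4C (1.68) and HIST1H2AE (1.63) were the 3 largest named increases, and the histone list had a median of 0.75 over 18 genes (percentile 100) with 3 higher and 0 lower. Histone genes are near-identical paralogs and their messages lack a poly(A) tail, so their levels are uncertain in libraries selected on poly(A). The complement receptor C5AR1 (1.45), the integrin ITGAX (1.43) and CRIP1 (1.36) were also higher. CCR4 (-1.44), NPR3 (-1.43), CD52 (-1.20), ADAM28 (-1.07) and GYLTL1B (-1.03) were lower. Against the mean of the 3 controls CCR4 (-0.91), ADAM28 (-0.99) and CRIP1 (0.97) no longer passed, nor did GYLTL1B (-0.97) with a pseudocount of 1.

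HEB knockdown moved few genes, with 23 higher and 49 lower, where a simulated unchanged library gave a mean of 56.2 past the rule. Of 36 lower genes that were also measured in the double knockdown, 30 were lower there too, against 0.935 for independent lists. Of 5 such higher genes, 0 were higher there. The rule uses all 3 controls for both lists, so they are not fully independent. None of the higher genes reached 5 RPKM. METTL7B (-1.79), ID3 (-1.74), the tight junction protein CGN (-1.54), DPEP1 (-1.41), DUSP27 (-1.39), RASGRP4 (-1.26), CD48 (-1.24) and GYG2 (-1.21) were lower, as was PRRT2 (1.77 against 5.92 RPKM). Against the mean of the 3 controls METTL7B (-1.05), RASGRP4 (-0.91), GYG2 (-0.99) and PRRT2 no longer passed. ITGA2B, a platelet integrin, was lower by -1.14.

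The double knockdown of HEB and E2A gave 66 higher and 335 lower genes, 144 and 203 with quantile normalization, and 69 and 1150 against the mean of the 3 controls. CD48 went from 14.2 to 1.19 RPKM (-3.11) and ID3 from 6.58 to 0.397 (-2.98), beside -1.24 and -1.74 in shHEB and -2.18 and -1.84 in shE2A. SPINK4 (-3.23), GYLTL1B (-3.19), FLT1 (-2.66), FSD1 (-2.65), SCARNA22 (-2.55), DUSP27 (-2.54) and ADARB2-AS1 (-2.46) were also lower, as were NPR3 (-2.24), IL1B (-1.98), the complex member TAL1 (-1.01) and CEBPA (-1.03), a factor of granulocyte development. Thrombospondin THBS1 (1.58), OLIG1 (1.69), DYSFIP1 (1.57) and ARSG (1.56) were higher, SESN3 reached 19.9 RPKM against 6.71, and 5 of the 10 largest increases were microRNA genes of at most 106 bases. Control 3 was the lowest of the 3 controls for all 10 named increases. Against the mean of the controls 7 of them no longer passed, among them THBS1 (0.85), ARSG (0.76) and SESN3 (0.67), while all 10 named decreases still passed. That mean includes the deep controls 1 and 2, and depth by itself lowers many genes of a shallow library against them. The comparison therefore cannot tell depth from the knockdown, for the increases or for the decreases. LYZ, which encodes lysozyme, reached 76.4 RPKM (1.25). Both libraries of this set were shallow, and control 3 itself had 1441 genes lower and 10 higher than control 1 by the limit of 1 on the log2 scale.

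Of the 327 lower genes of the double knockdown measured in all 3 knockdowns, 70.9% were lower in both single knockdowns, where random genes of matched expression gave a mean of 26.5%. The median change was -1.32 in the double knockdown, -0.36 in shHEB and -0.39 in shE2A. These genes were chosen for their fall in the double knockdown, so a larger median there is built in. Of 45 higher genes, 73.3% were higher in both singles. The difference between double and single knockdowns was not tested, since each is 1 library.

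Most genes passed the rule in a single knockdown: 620 were higher and 586 lower in at least 1, 191 and 186 in at least 2, and 32 were higher in some knockdowns and lower in others. A few recurred. CSF1R was higher in 6 of 7, all but shHEB (-0.18), and the metalloproteinase MMP28 was lower in 7 of 7, from -1.26 in shHEB to -2.73 in shAML1-ETO. HEMGN, CCR4, NPR3, OLFML2A and BTN1A1 were lower in 6, with HEMGN, a nuclear protein of blood progenitors, between -2.39 and -3.11 in those 6. SELPLG, SLC16A3, C1QTNF6, HEATR8 and MIR4489 were higher in 5. These genes were singled out after their values were seen. In all, 63 genes were higher and 79 lower in at least 3 knockdowns. The 5 knockdowns with control 1 also share its chance values, so part of this recurrence may come from that library.

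**Figure D2:**
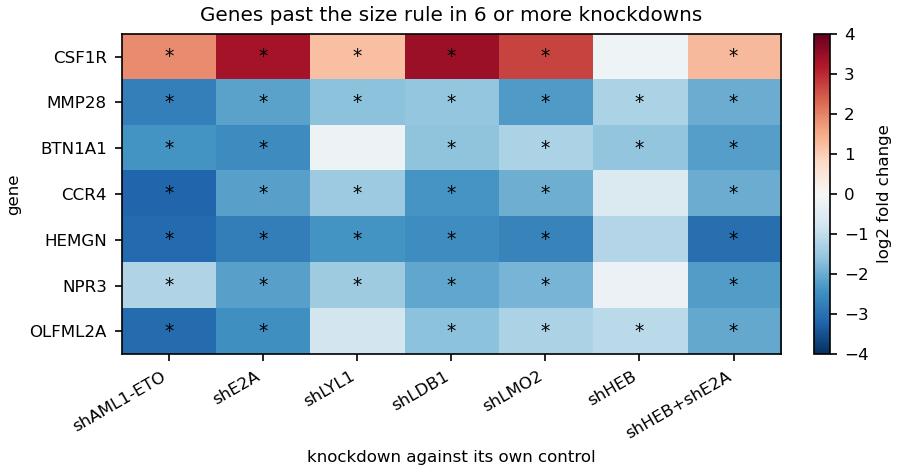
Log2 fold change (colour) of genes past the size rule in 6 or more of the 7 knockdowns, each against its own control; asterisks mark knockdowns where the gene passed. CSF1R was higher in 6 and MMP28 lower in 7.

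Between knockdowns that share control 1, the correlation of log2 fold changes across genes ran from 0.22 (shAML1-ETO with shLYL1) to 0.728 (shE2A with shLDB1), where unchanged libraries against 1 control gave 0.501. The median covariance was 0.0597, beside 0.0312 simulated. Between knockdowns with separate controls r ran from -0.0526 (shLYL1 with shHEB) to 0.504 (shE2A with the double knockdown), with a median of 0.342 and a simulated value of -0.00140. Noise in the simulation was independent in every library, so its correlations follow from its design. It cannot show what correlation other differences shared by the libraries would give. shE2A and shLDB1 shared 75 higher genes, against 1.48 for independent lists, and 41 lower genes, against 0.540; a pair of unchanged libraries with 1 control shared a mean of 8.21 genes in the simulation. shAML1-ETO and the double knockdown, which share no control, had 111 lower genes in common, against 6.54 for independent lists, and 11 higher, against 0.511, while 11 passed in opposite directions. Genes are not independent replicates, so these values carry no p.

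Across all 7 knockdowns and 3 controls limma called 0 genes at an adjusted p under 0.05, with 1968 of 13719 at an unadjusted p under 0.05. The unadjusted number fell to 552 without the double knockdown, 555 without control 3 and 557 of 13707 without both. It therefore rested largely on the shallow set. Camera called 6 gene lists at a preset correlation, and 0 with an estimated correlation (adjusted p = 0.687 to 0.747 for these 6) or in the directional test of fry (adjusted p = 0.155 to 0.631). The mixed test of fry, which asks for change in either direction, called 1 list, the erythroid genes (adjusted p = 0.0217, median -0.10). Only 6 of the 23 genes of that list were measured. HEMGN changed by -2.37 and the others by -0.37 to 0.39. At the preset correlation ribosomal protein genes lay higher (median 0.15; adjusted p = 1.48e-05; median above 0 in 5 of 7 knockdowns), as did granule genes (0.19; adjusted p = 0.000482; 7 of 7), monocyte genes (0.25; adjusted p = 0.00230; 7 of 7), respiratory chain genes (0.07; adjusted p = 0.00520; 3 of 7) and antigen presentation genes (0.15; adjusted p = 0.0303; 7 of 7), and stem and progenitor genes lay lower (-0.17; adjusted p = 0.0243; below 0 in 7 of 7). The double knockdown stood apart for 2 of these lists: ribosomal protein genes had a median of 0.49 there and at most 0.12 in the other 6, and respiratory chain genes 0.26 there and at most 0.03 elsewhere. Abundant genes lay higher in that library in general, with a median of 0.30 for housekeeping genes and 0.10 for all genes above 40 RPKM. Against the mean of the 3 controls the granule list turned to -0.00364 in shLMO2, the monocyte list to -0.03 in the double knockdown, and the ribosomal list to -0.03 in shAML1-ETO and -0.08 in shHEB. No single member passed the threshold. Adjusted over the list alone, 2 monocyte genes, 1 p53 gene and 1 glycolysis gene rose. By the same adjustment 2 stem and progenitor genes, 2 complex members (TAL1 and TCF12) and 1 erythroid gene fell. TCF12 is the gene that the hairpins against HEB target (-0.37 in shHEB, -0.56 in the double knockdown). Its fall is thus at least partly built in.

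**Figure D3:**
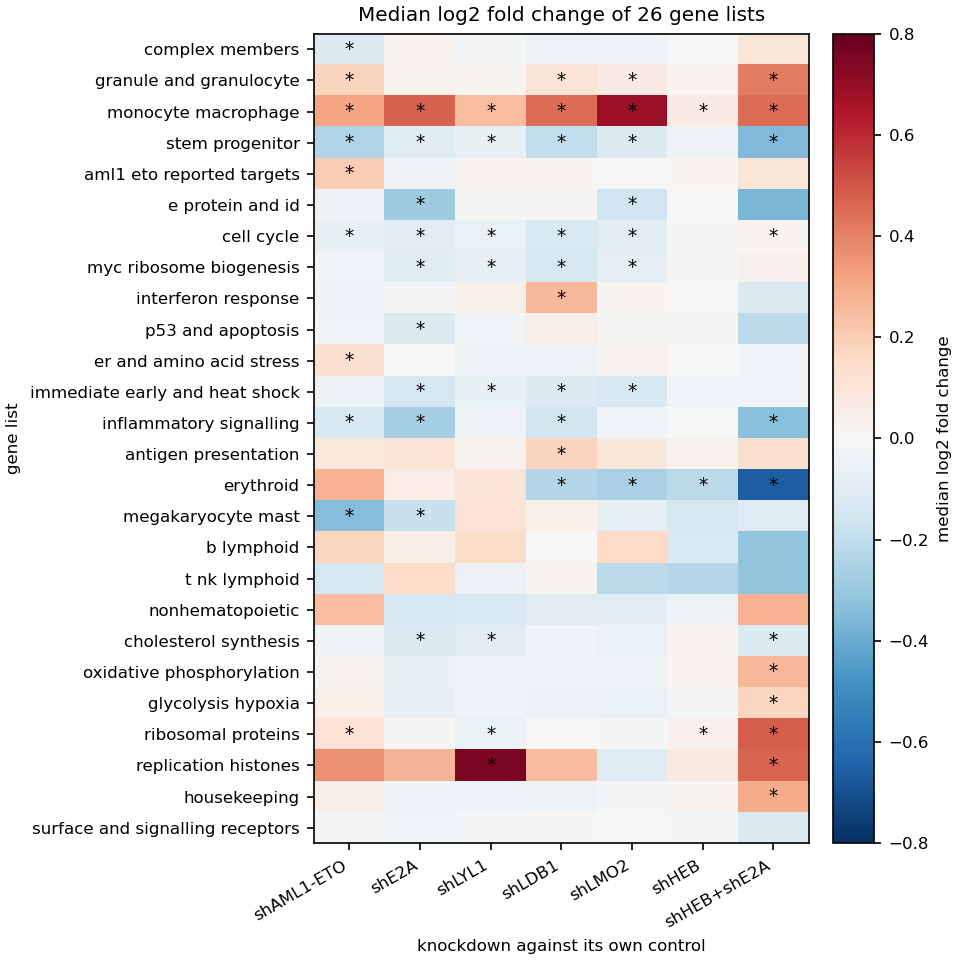
Median log2 fold change (colour) of 26 gene lists in each knockdown against its own control; asterisks mark medians beyond 95% of random lists matched on expression. The monocyte list lay above 0 in all 7 knockdowns, from 0.07 in shHEB to 0.69 in shLMO2, but at -0.03 in the double knockdown against the mean of the 3 controls.

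Immediate early genes differed between the controls themselves. FOS was 26.8 RPKM in control 1, 14.5 in control 2 and 1.93 in control 3, and between 2.97 and 3.59 in shE2A, shLYL1, shLDB1 and shLMO2. None of these FOS values passed the rule, because the controls differed by more.

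Most peaks of AML1-ETO, HEB and LMO2 overlapped a peak of another factor, whereas 68.6% of E2A peaks overlapped none. The lists held 15591 peaks for AML1-ETO, 10736 for HEB, 47266 for E2A and 6787 for LMO2. Of HEB peaks, 72.5% (95% interval 71.7 to 73.4) overlapped an AML1-ETO peak and 87.9% (87.3 to 88.5) an E2A peak. Of AML1-ETO peaks, 71.3% (70.6 to 72.1) overlapped E2A and 48.7% HEB. Of LMO2 peaks, 94.8% (94.2 to 95.3) overlapped E2A, 65.6% HEB and 58.3% AML1-ETO. Random shifts gave at most a mean of 1.25% for any pair. They move peaks to any place in a chromosome's span. They therefore cannot show how much overlap a shared preference for accessible sites alone would give. Peaks of LMO2 that met all 3 other factors numbered 3380, or 49.8%. The thresholds of the lists set this share, which was 31.6% with lists of equal length and 87.5% with heights of at least 15, and the share of LMO2 peaks with AML1-ETO was 36.7% and 88.6%. Merged into 51680 regions, 3383 held all 4 factors and 32444 held E2A alone.

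Taller peaks overlapped more often. Among LMO2 peaks the share meeting all 3 other factors went from 13.3% in the lowest quintile of height to 90.3% in the highest, and among HEB peaks from 7.45% to 70.9%. Among AML1-ETO peaks overlap with HEB went from 23.3% to 84.6%. The strongest shared peaks by the sum of ranks lay, on hg18 and as the AML1-ETO list gives them, on chromosome 1 from 158146752 to 158147217 and from 27311034 to 27311719, chromosome 22 from 18258367 to 18259750, chromosome 17 from 70287662 to 70288381 and chromosome 16 from 56280898 to 56281699. At the first of these the heights were 166 for AML1-ETO, 194 for HEB, 337 for E2A and 102 for LMO2. Lists of different length and threshold do not rank the factors against each other, and the peaks were not assigned to genes.

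**Figure D4:**
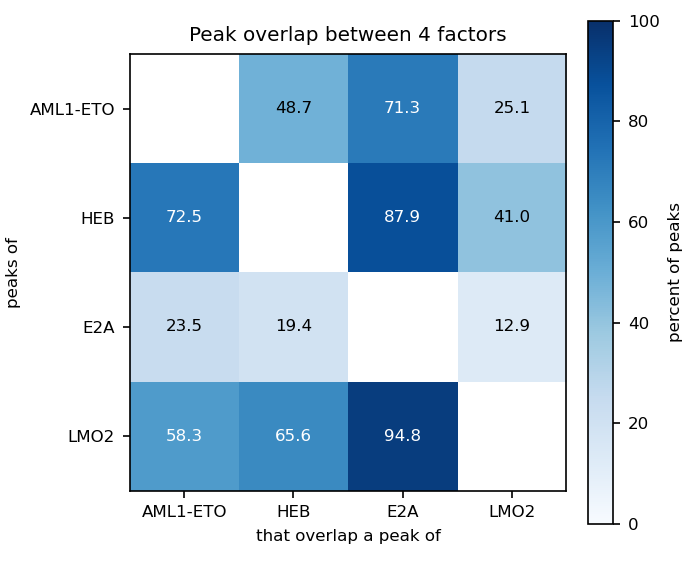
Percent of the peaks of 1 factor (vertical axis) that overlap a peak of another factor (horizontal axis) by at least 1 base. The highest share was 94.8% of LMO2 peaks with E2A and the lowest 12.9% of E2A peaks with LMO2.

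**Figure D5:**
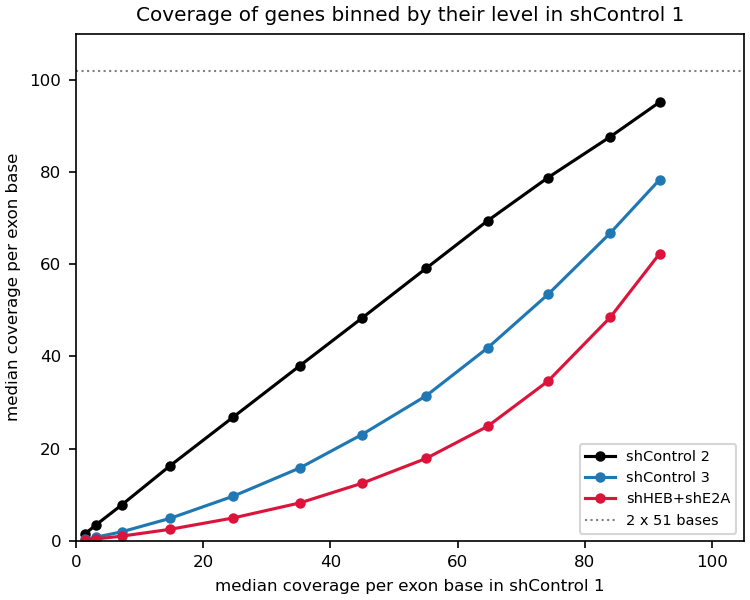
Median coverage per exon base in control 2, control 3 and the double knockdown (vertical axis) for genes binned by their coverage in control 1 (horizontal axis); the dotted line marks 102. In the highest bin control 1 stood at 91.8, control 3 at 78.4 and the double knockdown at 62.3.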

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

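The ceiling-corrected values, quantile normalization for the size rule and the fit without the shallow libraries were chosen only after the results were seen. Of the 97 named changes in RPKM, all kept their direction under the 7 alternatives of pseudocount, scaling, ceiling and control. They also stayed past the size rule, except 17 with the mean of the 3 controls, 4 with a pseudocount of 0.1 and 1 with a pseudocount of 1. Fold enrichment of at least 4 was not run because no column was identified as fold enrichment, and the alternatives for genes with a peak were not run because no hg18 annotation was used here. Depth limits the double knockdown and its control most, and the coverage ceiling limits abundant genes such as the hairpin targets.

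The number of genes past the size rule moved as follows, and where no reason is given the cause was not tested. With a pseudocount of 1 it was 66 for shLMO2 and 42 for shHEB. With an RPKM of at least 5, which leaves fewer genes, it was 311 for shAML1-ETO, 98 for shE2A, 18 for shLYL1, 128 for shLDB1, 28 for shLMO2, 20 for shHEB and 217 for the double knockdown. With a limit of 1.5, which is stricter by construction, it was 293, 99, 27, 120, 36, 13 and 151 in the same order. With the mean of the 3 controls it was 139 for shLYL1 and 1219 for the double knockdown. Without the condition on the controls, which can only add genes, it was 397 for shE2A, 135 for shLYL1, 503 for shLDB1, 183 for shLMO2 and 124 for shHEB. Quantile normalization turned the share of higher genes from 61.4% to 50% in shE2A, from 86.0% to 60% in shLYL1, from 76.0% to 65.3% in shLDB1 and from 16.5% to 41.5% in the double knockdown.

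In the limma fit of the common effect, 1 gene passed without a low-value filter, 3 with quantile normalization, 1 with ceiling-corrected values, 1 without shHEB, 1 without control 2 and 0 without any other library. It was also 0 with no block for the control set (597 at an unadjusted p under 0.05). With ceiling-corrected values camera at a preset correlation called 10 lists in place of 6, with cell cycle, MYC, cholesterol and histone genes added. The directional test of fry on the same values called none of the added lists (adjusted p = 0.338 to 0.589). In the fit against the 3 controls, shAML1-ETO had 289 genes with quantile normalization and 59 with ceiling-corrected values, and the double knockdown had 1 with an RPKM of at least 5. Without control 1 the counts were 81 for shAML1-ETO, 1 for shE2A, 2 for shLYL1, 19 for shLDB1, 4 for shLMO2, 4 for shHEB and 49 for the double knockdown. Without control 2 they were 133, 31, 6, 44, 15, 18 and 79 in the same order, and without control 3 they were 577, 0, 0, 0, 0, 0 and 10040. Without control 3 the shallow double knockdown stands only against the deep controls 1 and 2. Control 3, with no knockdown, had 99.3% of the genes past the size limit lower than in control 1. Its last count therefore cannot be told from depth. Other causes of these counts were not tested. The median correlation of knockdowns that share control 1 went from 0.585 to 0.327 when 1 of the 2 was set against another control, which removes the shared chance values. Gene lists beyond 95% of random lists numbered 6 for shHEB with ceiling-corrected values, and with the mean of the 3 controls 13 for shHEB, 6 for the double knockdown and 13 for shLMO2.

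Ceiling-corrected levels as percent of own control were 72.8% for RUNX1T1 and 81.0% for RUNX1 in shAML1-ETO, 54.9% for TCF3 in shE2A, 64.9% for LYL1, 63.2% for LDB1, 74.0% for LMO2 and 65.1% for TCF12 in shHEB. In the double knockdown they were 62.6% for TCF12 and 64.2% for TCF3. The correction stretches high values by construction. With an overlap of at least 0.5 of the smaller peak, 70.8% of HEB peaks met AML1-ETO, 62.3% of AML1-ETO peaks met E2A, 56.0% of LMO2 peaks met AML1-ETO, 81.7% of HEB peaks met E2A, 63.2% of LMO2 peaks met HEB and 47.4% of LMO2 peaks met all 3. With centres within 500 bases the first 5 were 74.4%, 76.8%, 60.8%, 90.7% and 68.0%, and 92.6% of LMO2 peaks met E2A. With heights of at least 15, which keeps the tallest LMO2 peaks, LMO2 met AML1-ETO at 88.6%, HEB at 98.0%, E2A at 99.7% and all 3 at 87.5%. With as many peaks from every list as the shortest holds, HEB met AML1-ETO at 57.1%, AML1-ETO met E2A at 51.7%, LMO2 met AML1-ETO at 36.7%, HEB met E2A at 73.1%, LMO2 met HEB at 54.7%, LMO2 met E2A at 66.8% and LMO2 met all 3 at 31.6%.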

Other observations

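The tests of the coverage ceiling, of depth in the double knockdown, of S phase, of the narrower set of RNA without a poly(A) tail and of other splits for single genes were chosen only after the results were seen. In further knockdowns, CD109, a surface protein of progenitors, was lower in shE2A (-1.19) and the double knockdown (-1.73), and MYCN was lower in the double knockdown (-1.17). ICAM1, an adhesion molecule, was higher in shLYL1 (1.21), unlike in shE2A, and lower in shAML1-ETO (-1.23). In the double knockdown ribosomal protein genes had a median of 0.49 (percentile 100), although 0 of 25 passed the rule, and granule genes a median of 0.41 with 0 of 20 higher and CEBPA lower. Beside the 4 turns given above, the histone list of the double knockdown went from 0.47 to -0.69 against the mean of the 3 controls, its cholesterol list from -0.11 to 0.21, the erythroid list of shHEB from -0.22 to 0.00 and the p53 list of shE2A from -0.11 to 0.04. With ceiling-corrected values the erythroid list of shLMO2 went from -0.26 to 0.10 and the cell cycle list of the double knockdown from 0.02 to -0.05.

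For the common effect the real split gave 0 genes with limma (1968 at an unadjusted p under 0.05). With 0 genes, every other split gives at least as many, so the 24 of 24 splits that take 1 library per set as control and the 100 of 100 drawn from 120 splits into 3 and 7 decide nothing. The highest other counts were 49 and 2247 genes, the last with shHEB, control 2 and the double knockdown as controls. With the control set as a block, that split rests on the double knockdown against control 3 alone, both shallow. The source of its count was not tested. The 6 lists called by camera with a preset correlation were matched or passed in 13 of 24 splits, up to 11 lists. Chance is therefore not excluded for the lists.

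In shLYL1 the replication-dependent histone genes, whose messages lack a poly(A) tail, had a median of 0.75 (1.13 against the mean of the 3 controls), beside 0.36 in shAML1-ETO, 0.27 in shE2A, 0.25 in shLDB1 and -0.10 in shLMO2, which share its control. If that library held more RNA without a tail, other such genes would be higher too. Over all 250 the median was -0.0757 (bootstrap interval -0.117 to -0.0395). This does not decide, since that median was below 0 in all 5 knockdowns with control 1 (-0.12 to -0.01). In addition, 234 of the 250 genes were under 200 bases. After that result was seen, the set was narrowed to genes of at least 200 bases. Those 16 genes had a median of 0.17 (0.03 to 0.53). That set stood at 0.36 in shAML1-ETO, 0.19 in shLMO2, 0.12 in shE2A and -0.02 in shLDB1. It therefore stays open whether longer RNA of this kind was enriched. More cells in S phase would raise the cell cycle list, whose median was -0.0504, but that list lay low in all 5 knockdowns with control 1 (-0.12 to -0.05), so this stays open. Reads shared between histone paralogs and an effect of LYL1 itself were not tested and stay open.

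The double knockdown had 66 higher and 335 lower genes, and 144 and 203 with quantile normalization. Control 3, with no knockdown and also shallow, had 99.3% of the genes past the size limit lower than in control 1, so depth together with the ceiling may account for part of the imbalance. Depth and the ceiling alone do not explain which genes were lower, since 70.9% of them were lower in both single knockdowns, against at most 34.3% in 1000 random gene sets. An effect of losing both E proteins stays open as a hypothesis.

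Coverage of abundant genes such as MPO levelled off in every library. A curve with only 1 read kept per start position and strand was fitted to control 3 against control 1. Its mean error was 0.344 on the log2 scale, where a straight line had 0.433, so removal of duplicate reads may be the source. MPO coverage of 107.5 to 125.7 lay above the 102 that such a curve allows, so the curve is approximate at best. The top 100 genes held at most 6.04% of the bases, but these bases are already flattened, so the value cannot tell whether a few genes took most of the reads before. No biological explanation of this flattening was tested.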
